A study of Arabidopsis thaliana with 8 samples.

How the data were processed

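Total RNA was extracted with a phenol-based reagent, treated with DNase and made into libraries with a strand-specific kit, per the labels' protocols. The authors deposited 1 table of FPKM values with 34354 rows and a column for each of the 8 libraries. TopHat, TopHat2 and edgeR are listed as tools and TAIR10 as the genome build, per the submitters' processing notes, with no versions or roles. The counting program, its annotation, its use of strand and any filter are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart with certainty. Of the row identifiers, 32548 matched a locus in the TAIR10.1 annotation, which was used for gene symbols and gene lengths and from which no coordinates are given. By their definition the deposited FPKM are scaled to library totals, so a group of abundant genes that moves shifts all other values.

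Where whole reads were counted, FPKM are whole multiples of the value of 1 read in a gene. These steps gave whole reads for 99.8% of the 23543 rows above 0 in any library (within 0.1 of a whole number). Depth followed from annotated lengths: 8630 of 17194 genes gave the same depth, 16852240 to 29535916 reads per library. At that depth 1 read in a gene of 1500 bp was worth 0.0226 to 0.0396 FPKM. The libraries of each pair differed by more than sampling noise, with a mean chi-square per gene of 4.77 in wild-type mock, 2.09 in wild-type heat, 4.54 in mutant mock and 2.06 in mutant heat, unlike repeated deposits of 1 library. That they are biological replicates is taken from the series' design text.

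Groups were taken from the sample titles. Because FPKM are not counts, log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend). A model of group means over all 8 libraries left 4 residual degrees of freedom, and genes with at least 1 FPKM in at least 2 libraries were kept. There were 5 two-sided comparisons: heat against mock in each genotype, mutant against wild type in mock and after heat, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The design, the alternatives, 23 gene lists and the rule for named genes were fixed before the data were examined. Of 378 list entries 1 was left out because its symbol belongs to another locus. The 22 lists with at least 3 measured members were tested with camera (preset correlation 0.01, adjusted over lists within each comparison), and with an estimated correlation and fry as alternatives. In 15 of 110 list tests, none of them called by camera, the median and the direction of camera had opposite signs. The lists cover PIF-related bHLH genes, senescence-associated genes, senescence transcription factors, chlorophyll breakdown and synthesis, nuclear photosynthesis, heat shock, ethylene, abscisic acid, auxin and growth, jasmonate, salicylic acid, cytokinin, autophagy, nitrogen remobilisation, anthocyanin, oxidative stress, the clock, cell division, and guard cell, vascular, epidermis and shoot meristem markers.

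Named genes are 13 key genes with PIF4 and PIF5 among them, up to 4 passing members per list with the smallest p (or 2 as values where none passed), and outside the lists the 6 largest changes in each direction among passing genes with a symbol, non-overlapping libraries and a mean of at least 5 FPKM in the higher group. For the interaction, the same sign in both replicate numbers replaced non-overlap.

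The test was checked on simulated reads drawn from the real means and depths, with 200 genes changed by known folds among 16789. For heat in the wild type it called 76.8% of genes changed 1.5-fold, 95.9% at 2-fold and 100% at 4-fold, and for the interaction 55.7%, 84.1% and 95.5%. These right calls numbered 43, 70 and 71 for heat in the wild type and 39, 53 and 64 for the interaction. Beside them, false calls among 16589 unchanged genes numbered 15 and 13. The simulated median SE was 0.0793 against 0.0920 in the data for heat in the wild type, and a larger spread lowers the share called. But the data had 6468 calls there, many more than the 200 genes changed, and more calls make the adjusted threshold less strict. The shares are therefore neither upper nor lower guides to the data. All simulated genes also had the same spread between replicates beyond sampling noise. Alternatives were another pseudocount, filters, scalings, a replicate block, only the compared groups, no trend, library weights, a fold threshold and each library left out. Limma-voom on the recovered reads was added after the data were seen, as were 4 further gene lists. Figures were drawn with matplotlib 3.10.9.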

Results

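Gene expression was measured by RNA sequencing in leaves of Arabidopsis thaliana, comparing the Col-0 wild type with the pif4-2 pif5-3 double mutant, which carries mutations in PIF4 and PIF5. Both genes encode basic helix-loop-helix transcription factors that act in light and temperature signalling. Soil-grown plants aged 3 weeks and kept at 22 °C were either mock-treated, or exposed to 42 °C for 5 h and left to recover for 3 days. The third and the fourth rosette leaf were taken. The recovery time was recorded here for the heat groups only, so an equal age of the mock leaves at harvest was not checked. The 4 groups of wild-type mock, wild-type heat, mutant mock and mutant heat held 2 libraries each, which the labels number as biological replicates. The values are FPKM (fragments per kilobase of transcript, scaled to the mapped reads of the library). The depth recovered from their steps ran from 16852240 to 29535916 reads per library, and between 16016 and 16348 genes reached 1 FPKM. FPKM are given as mean ± SD (n = 2) and changes as log2 change ± SE on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. Adjusted p-values are Benjamini-Hochberg values from limma over 16831 genes.

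The mutated genes were examined first. PIF4 (AT2G43010) was at 131 ± 0.0201 FPKM in wild-type mock, 98.97 ± 2.57 in wild-type heat, 33.6 ± 0.0192 in mutant mock and 24.7 ± 1.28 in mutant heat. PIF5 (AT3G59060, PIL6 in the annotation) was at 64.8 ± 2.23, 54.6 ± 0.391, 5.15 ± 0.637 and 4.36 ± 0.538 FPKM in the same order. The mutant was lower in mock by a log2 change of -1.94 ± 0.05 for PIF4 (adjusted p = 2.4e-10) and -3.42 ± 0.09 for PIF5 (adjusted p = 2.4e-10). All 4 mutant libraries lay below all 4 wild-type libraries for both genes. Gene-level FPKM does not show which part of the PIF4 transcript the remaining reads come from. PIF4 fell after heat in both genotypes, by 0.41 ± 0.05 in the wild type and by 0.43 ± 0.05 in the mutant on the log2 scale, with no difference between these changes past the threshold (interaction -0.0205 ± 0.07, adjusted p = 0.85).

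**Figure D1:**
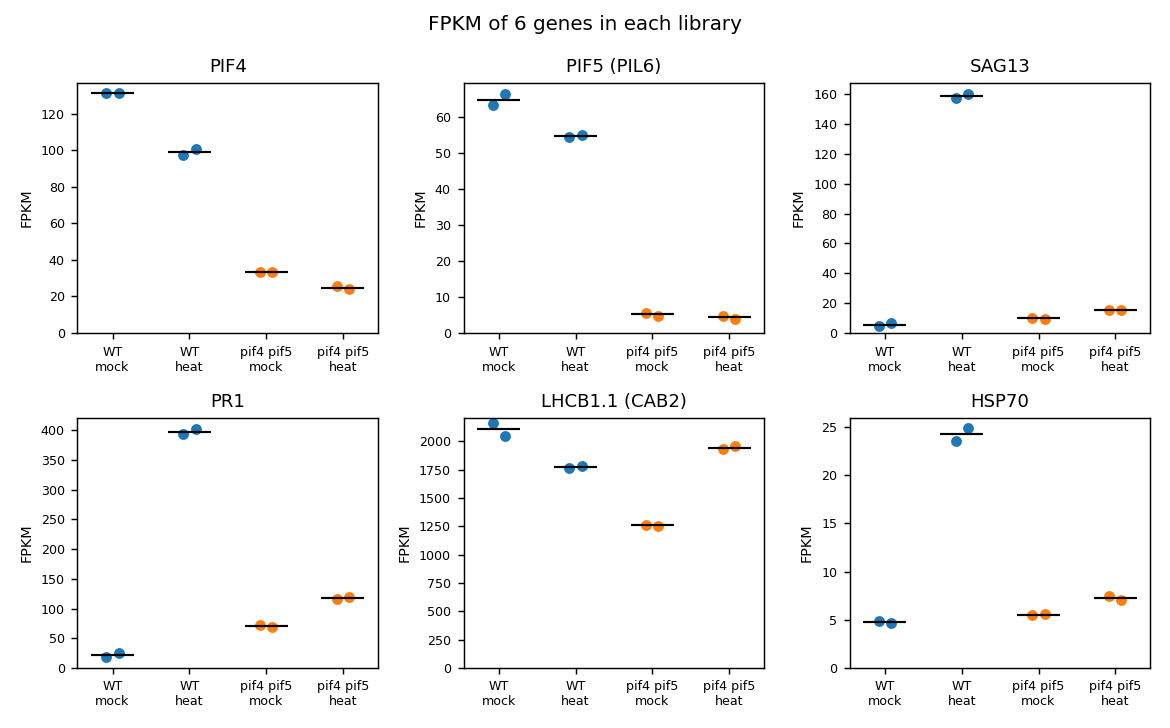
Each panel plots the FPKM of 1 gene (vertical axis, starting at 0) in the 4 groups (horizontal axis), with a point per library and a line at the mean of the 2 libraries. SAG13 reaches a mean of 159 FPKM in wild-type heat and 15.42 in mutant heat, while LHCB1.1 (CAB2) has its lowest mean, 1259 FPKM, in mutant mock.

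The comparison of heat with mock in the wild type asked which transcripts differ 3 days after heat stress. The series' design text says that the collected leaves had begun to yellow at their edge, without naming the groups. Senescence-associated genes rose: 14 of 18 measured members were higher and 1 lower, with a median log2 change of 1.18. SAG13, a senescence marker encoding a short-chain dehydrogenase, went from 5.46 ± 1.53 to 159 ± 1.495 FPKM (log2 change 4.65 ± 0.12, adjusted p = 4.4e-11). BCB (SAG14), a blue copper protein gene, went from 29.7 ± 2.25 to 199.96 ± 9.30 FPKM, and the ribonuclease gene RNS1 from 0.179 ± 0.152 to 14.0 ± 0.0196 FPKM. SAG12 was below the filter on low values. Senescence transcription factors were higher in 18 and lower in 1 of 22 members (median 0.696), among them NAC019 (log2 change 3.29 ± 0.10), NAC047 (2.73 ± 0.15) and WRKY45 (2.297 ± 0.12). ORE1 (NAC6 in the annotation), a NAC regulator of leaf senescence, was at 7.16 ± 0.635 FPKM in mock and 8.55 ± 1.24 after heat and did not pass the test (adjusted p = 0.15). NAP, another NAC regulator of senescence, fell (-0.51 ± 0.14, adjusted p = 0.011), a call lost without wild-type mock replicate 2 (-0.47, adjusted p = 0.059) or wild-type heat replicate 2 (-0.47, adjusted p = 0.072).

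Genes of chlorophyll breakdown were higher in 7 and lower in 1 of 13 members, including NYE1, which encodes the magnesium-dechelating enzyme (0.59 ± 0.07), its paralog NYE2 (AT4G11910, 1.63 ± 0.09) and PAO (ACD1 in the annotation, 0.29 ± 0.05). Chlorophyll synthesis fell in 10 of 17 members, with PORB, a protochlorophyllide oxidoreductase gene, at -0.43 ± 0.04. Nuclear photosynthesis genes were lower in 37 and higher in 4 of 49 members (median -0.22), and with quantile scaling lower in 29 and higher in 8 (median -0.12). LHCB2.1, a light-harvesting protein gene, changed by -0.60 ± 0.06, and the photosystem I gene PSAK by -0.43 ± 0.05, whereas the Rubisco small subunit genes RBCS1A (0.31 ± 0.05) and RBCS2B (0.51 ± 0.04) rose. Reads of the LHCB and RBCS families can be shared between near-identical copies, so their single values are uncertain. Heat shock factors and chaperones were higher in 27 of 36 members and lower in 0. HSP70 went from 4.74 ± 0.104 to 24.3 ± 0.981 FPKM, HSP18.2 from 0.225 ± 0.0293 to 14.4 ± 2.43 FPKM, and HSP101, the disaggregase gene, changed by 0.92 ± 0.12.

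Salicylic acid and defence genes rose in 11 of 16 members. PR1 went from 21.1 ± 4.99 to 398 ± 5.48 FPKM (4.19 ± 0.10, adjusted p = 4.0e-11) and PR5 from 25.1 ± 0.944 to 117 ± 6.12 FPKM. All 9 measured anthocyanin genes rose (median 2.35, and 3.93 with a pseudocount of 0.1 FPKM or 4.01 with limma-voom on recovered reads), with the reductase gene DFR at 3.69 ± 0.14 and chalcone synthase (TT4) at 3.36 ± 0.14. Jasmonate genes were higher in 11 and lower in 3 of 16 members. The defensin gene PDF1.2, which shares reads with its paralogs, went from 5.66 ± 0.577 to 271 ± 27.8 FPKM, while VSP2 fell (-0.65 ± 0.08). Nitrogen remobilisation and dark-inducible genes were higher in 8 and lower in 2 of 15 members, with the nitrate transporter gene NRT1.7 at 0.87 ± 0.05. Autophagy genes were higher in 6 of 18 members, led by the receptor gene NBR1 (0.56 ± 0.04). Auxin and growth genes were lower in 9 and higher in 1 of 12 members, with IAA29 going from 15.3 ± 0.903 to 2.50 ± 0.495 FPKM, and cytokinin genes were lower in 5 and higher in 2 of 8 members, with the response regulator ARR6 at -1.35 ± 0.09. In the abscisic acid list 7 members rose and 6 fell, and NCED3, a gene of abscisic acid synthesis, fell (-0.93 ± 0.10).

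Outside the lists, the highest rises by the fixed rule were those of NIT2 (from 0.312 ± 0.0363 to 196 ± 27.4 FPKM), KTI1, EARLI1 (4.21 ± 0.250 to 319 ± 21.0 FPKM), ELI3-2, PDF1.2c and UPI. The strongest falls were those of TCH4 (-2.07 ± 0.09), PHI-1 (-2.06 ± 0.12), TGG2, SHY2, XTH6 and AGP41. In total 6468 genes changed after heat in the wild type, 3626 higher and 2842 lower, and 816 of them changed at least 2-fold, 661 higher and 155 lower; the share of higher calls was 56.1% as deposited, 52.3% with median-of-ratios scaling and 42.9% with quantile scaling. With a pseudocount of 0.1 FPKM 1250 genes changed at least 2-fold, 925 higher and 325 lower, and with limma-voom 1273, 950 higher and 323 lower. By camera with a preset correlation of 0.01, 14 lists were called. The calls of senescence transcription factors, heat shock genes, salicylic acid genes, auxin and growth genes and anthocyanin genes held with an estimated correlation (adjusted p = 0.047 for each). The others did not, with adjusted p = 0.064 with an estimated correlation for senescence-associated genes, 0.18 for chlorophyll breakdown, 0.099 for chlorophyll synthesis, 0.27 for photosynthesis, 0.088 for jasmonate, 0.088 for nitrogen remobilisation, 0.21 for autophagy and 0.11 for cytokinin. Epidermis markers also fell as a list (3 of 5 members, adjusted p = 0.2 with an estimated correlation), with ATML1 at -0.89 ± 0.07.

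In the pif4 pif5 mutant the same comparison was made with its own mock libraries. Senescence-associated genes were higher in 3 and lower in 2 of 18 members, with SAG13 going from 9.72 ± 0.559 to 15.42 ± 0.145 FPKM (0.62 ± 0.12, adjusted p = 0.0044) and BCB changing by 0.63 ± 0.06. Senescence transcription factors rose in 5 of 22 members, or 2 without mutant mock replicate 2 and 3 without mutant heat replicate 1 or 2, a filter on low values or an intensity trend. The breakdown genes NYE1 (0.14 ± 0.07, adjusted p = 0.16) and PAO (-0.12 ± 0.05, adjusted p = 0.085) did not pass, although NYE1 did with median-of-ratios (0.22, adjusted p = 0.045) and with quantile scaling (0.23, adjusted p = 0.042). Nuclear photosynthesis genes rose in 39 of 49 members (median 0.21), including LHCB1.1 (CAB2, 0.63 ± 0.04), LHCB2.3 (0.697 ± 0.04), LHCB3 (0.39 ± 0.04) and RBCS1A (0.43 ± 0.05). Without mutant mock replicate 2 23 were higher, without mutant heat replicate 1 23, without mutant heat replicate 2 20, without a filter on low values 24 and without an intensity trend 20. With quantile scaling 19 of the 49 members were higher, with LHCB3 at 0.18 and RBCS1A at 0.23, and with median-of-ratios scaling 44. Heat shock genes were higher in 9 and lower in 1 of 36 members, with HSP18.2 at 2.44 FPKM after heat. Their median was only 0.017 (0.0779 with median-of-ratios and 0.0718 with quantile scaling), against -0.0648 over all genes as deposited. Salicylic acid genes were higher in 6 and lower in 1 of 16 members, with PR1 at 0.74 ± 0.10 and PR5 at 0.82 ± 0.05. Of the jasmonate genes 2 rose and 6 fell, VSP1 going from 19.6 ± 2.86 to 3.23 ± 0.0465 FPKM. The number that fell was 3 without mutant heat replicate 1 or 2 or with median-of-ratios scaling. The autophagy list was not called (adjusted p = 0.2), but was without mutant mock replicate 1 (adjusted p = 0.048).

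Outside the lists, LTP4, SAE1B, EARLI1 (1.73 ± 0.09), EXT4, PHI-1 (1.68 ± 0.12) and PDF1.2c had the highest rises in the mutant, and MBP1, BGLU18 (-1.05 ± 0.04), MIOX1, FER1 (-0.85 ± 0.04), AACT1 and MYB47 the strongest falls. The SAE1B call was lost without mutant mock replicate 2 (adjusted p = 0.055), without a filter on low values (adjusted p = 0.074) or without an intensity trend (adjusted p = 0.054). Its change of 2.205 ± 0.50 was 1.03 without mutant heat replicate 1 and 3.38 without mutant heat replicate 2. In total 3401 genes changed, 1057 higher and 2344 lower, and 68 changed at least 2-fold, 48 higher and 20 lower (13 lower without mutant heat replicate 2 or without a filter on low values); the share of higher calls was 31.1% as deposited, 59.7% with median-of-ratios scaling and 48.0% with quantile scaling. Of at least 2-fold there were 112 higher and 58 lower genes with a pseudocount of 0.1 FPKM, and 125 and 51 with limma-voom. The count of changed genes was 1453 without mutant mock replicate 2, 1510 without mutant heat replicate 2 and 1855 without mutant heat replicate 1. Camera called 5 lists with the preset correlation and 0 with an estimated one (4 at an unadjusted p under 0.05), where the adjusted p was 0.21 for photosynthesis, 0.2 for salicylic acid, heat shock and senescence transcription factors, and 0.45 for epidermis markers (4 of 5 members lower). The preset call of the epidermis list was lost without mutant heat replicate 2 (adjusted p = 0.061). Its lower members numbered 1 there and 2 without mutant mock replicate 1, with median-of-ratios scaling or without an intensity trend.

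**Figure D2:**
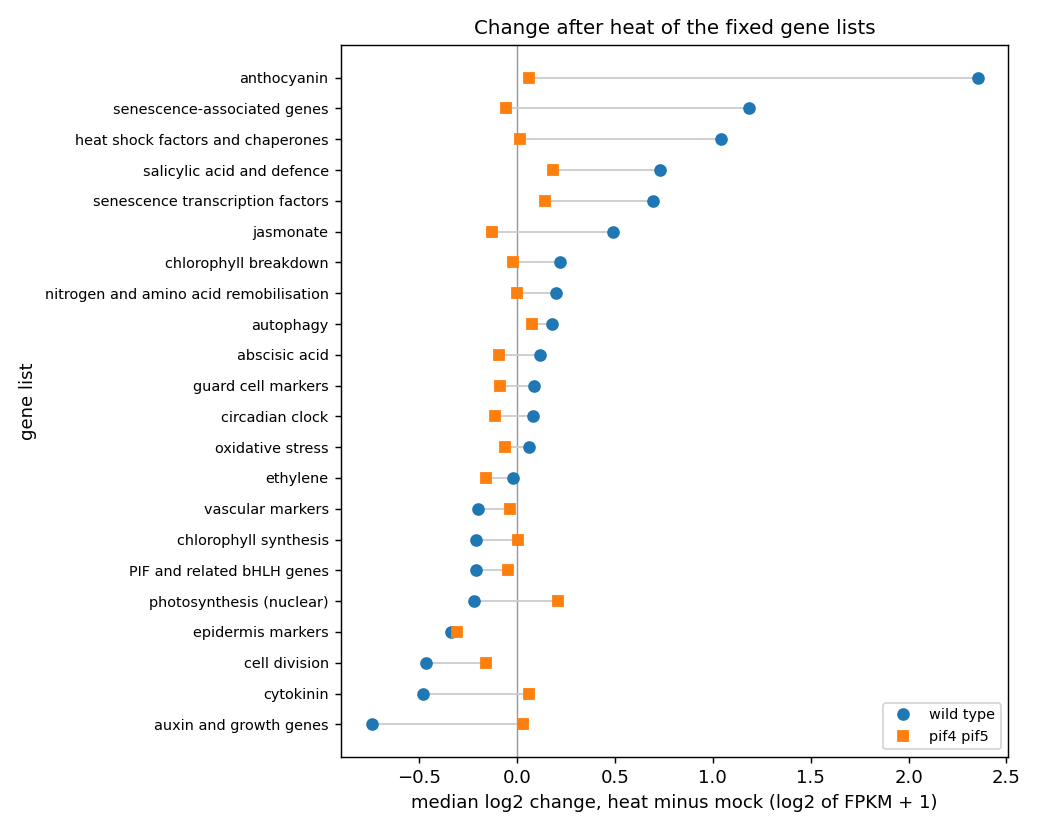
Median log2 change from mock to heat (horizontal axis, log2 of FPKM + 1) of the measured members of each fixed gene list (vertical axis), as circles for the wild type and squares for pif4 pif5. The anthocyanin list has a median of 2.35 in the wild type and 0.0609 in the mutant, and the photosynthesis list -0.22 and 0.21, which were -0.12 and 0.0524 with quantile scaling.

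To set the responses side by side without choosing and reading genes in the same libraries, genes were chosen by a change of at least 2-fold in one replicate number and read in the other. Of 706 genes higher after heat in wild-type replicate 1, the median log2 change in replicate 2 was 1.43 in the wild type and 0.19 in the mutant. With the replicates exchanged, 675 genes gave 1.47 and 0.14. For genes lower in the wild type the medians were -1.05 and -0.16 (189 genes), and -1.07 and -0.13 (176 genes). Chosen in the mutant instead, 66 and 56 higher genes had medians of 0.88 and 0.96 in the mutant and 0.31 and 0.77 in the wild type, and 23 and 43 lower genes had -0.67 and -0.41 in the mutant and -0.30 and -0.0835 in the wild type. With a pseudocount of 0.1 FPKM the order turned for higher genes chosen in the mutant: 176 and 185 genes had medians of 0.85 and 0.85 in the mutant and 0.94 and 1.46 in the wild type. The lower ones were at -0.0218 and -0.10 in the wild type, and higher genes chosen in the wild type at 0.22 and 0.22 in the mutant. Choosing by 4-fold left 4 and 3 higher genes from the mutant, at 0.26 and -0.26 in the wild type, and 7 and 4 lower genes from the wild type, which turned to 0.0144 and 0.99 in the mutant. With median-of-ratios scaling lower genes chosen in the wild type were at -0.0768 and -0.0677 in the mutant, and lower genes chosen in the mutant at -0.19 and -0.10 in the wild type. Across genes, which are not independent replicates, the heat changes of the 2 genotypes had a Pearson correlation of 0.28 and a Spearman correlation of 0.203. Among called genes 506 were higher in both genotypes, against 228 for independent lists, and 611 were lower in both, against 396. The higher genes numbered 302 against 117 without mutant mock replicate 2 and 297 against 126 without mutant heat replicate 2. The lower genes numbered 364 against 215 with median-of-ratios scaling, 336 against 243 and 346 against 152 without mutant mock replicates 1 and 2, and 387 against 206 and 272 against 152 without mutant heat replicates 1 and 2. Of 3626 genes higher in the wild type and 2344 lower in the mutant, 275 were both. The reverse held for 212, of 2842 lower in the wild type and 1057 higher in the mutant. No number for independent lists was set against these opposite changes, so neither is read as an excess. The heat comparisons of the 2 genotypes share no library, but both use the same estimate of the spread of each gene. A gene with a small spread is more easily called in both. The numbers for independent lists are therefore only a rough guide, and the shared calls are not a tested excess.

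Between the genotypes under mock conditions, salicylic acid and defence genes were higher in the mutant in 13 of 16 members, with PR1 at 1.705 ± 0.10, PR2 (BGL2) at 1.60 ± 0.05 and CBP60G, a regulator of salicylic acid synthesis, at 0.99 ± 0.07. Jasmonate genes were higher in 11 and lower in 1 of 16 members, with OPR3 at 0.48 ± 0.04 and JAZ5 at 1.16 ± 0.11. Auxin and growth genes were lower in 10 of 12 members, including IAA29 (-2.80 ± 0.13), SAUR22 (-2.23 ± 0.13) and EXPA8 (-0.65 ± 0.05). Photosynthesis genes were lower in 34 of 49 members (median -0.18), with CAB2 at -0.74 ± 0.04 and LHCB2.1 at -0.88 ± 0.06, while RBCS1A did not pass (-0.0720 ± 0.05, adjusted p = 0.33). With quantile scaling 17 photosynthesis genes were lower and 2 higher (median -0.0585). The number lower was 22 without wild-type mock replicate 1, 21 without mutant mock replicate 2, 19 without a filter on low values and 17 without an intensity trend or with only the compared groups in the fit. Senescence-associated genes were higher in 9 and lower in 2 of 18 members, with 3 higher without wild-type mock replicate 1 and 5 without mutant mock replicate 1. That list was not called (adjusted p = 0.093 by camera), but was with quantile scaling (adjusted p = 0.03), without wild-type mock replicate 2 (adjusted p = 0.034) and without mutant mock replicate 2 (adjusted p = 0.022). Senescence transcription factors (7 higher and 1 lower of 22, adjusted p = 0.38) and heat shock genes (7 and 2 of 36, adjusted p = 0.26) were not called, and the higher heat shock genes numbered 3 without mutant mock replicate 1 or a filter on low values and 4 with quantile scaling or without an intensity trend. The abscisic acid list had 4 lower and 0 higher of 18 members, with the cold-responsive COR15A going from 149 ± 5.97 FPKM in the wild type to 39.0 ± 1.69 in the mutant. HFR1, an atypical bHLH gene of light signalling, was at 16.1 ± 1.09 FPKM in the wild type and 0.0592 ± 0.0838 in the mutant.

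Outside the lists QQS (2.97 ± 0.08), CML41, MDHAR, CAX3, TAT3 and ERF13 were higher in the mutant, and MAF5 (-3.16 ± 0.13, with reads it can share with similar neighbours), ELI3-1, SAUR19, GolS2, PHI-1 and RD20 lower. In total 3479 genes differed, 2185 higher and 1294 lower in the mutant, and 175 differed at least 2-fold, 93 higher and 82 lower; the share of higher calls was 62.8% as deposited, 43.2% with median-of-ratios scaling and 47.1% with quantile scaling. The 2-fold numbers were 236 and 152 with a pseudocount of 0.1 FPKM, and 255 and 164 with limma-voom. The count of all that differed was 1781 without wild-type mock replicate 1 and 1836 without mutant mock replicate 2. Camera called 8 lists, and 1 of them, auxin and growth, held with an estimated correlation (adjusted p = 0.038). With it, adjusted p = 0.058 for salicylic acid, 0.069 for jasmonate and abscisic acid, 0.25 for photosynthesis and epidermis markers (3 of 5 lower, LTP1 (LP1) at -1.03 ± 0.06), 0.28 for chlorophyll breakdown (2 lower and 1 higher) and 0.3 for chlorophyll synthesis (2 lower and 1 higher). The preset calls of chlorophyll breakdown (adjusted p = 0.081) and synthesis (adjusted p = 0.14) were lost with quantile scaling, and that of breakdown also without wild-type mock replicate 1 (adjusted p = 0.08).

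After heat, senescence-associated genes were lower in the mutant than in the wild type in 14 of 18 members and higher in 1. SAG13 differed by -3.28 ± 0.12 (adjusted p = 1.4e-09), RNS1 by -3.46 ± 0.13 and SRG1 by -3.98 ± 0.15. Among senescence transcription factors 15 were lower and 4 higher of 22, with ORE1 at -0.65 ± 0.11 (adjusted p = 0.0012). Chlorophyll breakdown genes were lower in 8 of 13 members, among them NYE1 (-0.42 ± 0.07), PAO (-0.55 ± 0.05) and CYP89A9 (-0.81 ± 0.06), and chlorophyll synthesis genes higher in 8 of 17. The latter number was 4 without wild-type heat replicate 1 or 2 or mutant heat replicate 1, 5 without mutant heat replicate 2 and 3 without an intensity trend. Heat shock genes were lower in 22 and higher in 3 of 36 members, with HSP101 at -1.03 ± 0.12. All 9 anthocyanin genes were lower (median -2.08, and -4.15 with a pseudocount of 0.1 FPKM or -4.42 with limma-voom), and abscisic acid genes lower in 14 and higher in 2 of 18. The abscisic acid list was already lower in mutant mock, and was not called for the interaction (adjusted p = 0.61 by camera). There 10 of its members were negative and 5 positive, or 6 and 5 with quantile scaling. Nitrogen remobilisation genes were lower in 7 and higher in 2 of 15 members, with NRT1.7 at -0.91 ± 0.05. Photosynthesis genes were higher in 37 and lower in 1 of 49 members (median 0.24), and with quantile scaling higher in 20 and lower in 4 (median 0.0703). Cytokinin genes were higher in 5 and lower in 1 of 8, with ARR6 at 1.25 ± 0.09. CAB2 differed by 0.13 ± 0.04 (adjusted p = 0.025), a direction that turned with quantile scaling (-0.0112) and a call lost without any 1 of the 4 heat libraries (adjusted p = 0.1 to 0.15), without a filter on low values (adjusted p = 0.074) or without an intensity trend (adjusted p = 0.14). The salicylic acid list was split, 4 members higher and 6 lower (3 lower without mutant heat replicate 2), with PR1 at -1.75 ± 0.10.

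Outside the lists DIC2 (2.80 ± 0.08), ORA47, CAF1a, NUDT4, WRKY40 and PP2-A5 were higher in the heat-treated mutant, and NIT2 (-6.43 ± 0.12), KTI1, ELI3-2, UPI, PDF1.3 and CSLG2 lower. In total 4814 genes differed, 1855 higher and 2959 lower in the mutant, and 549 at least 2-fold, 95 higher and 454 lower; the share of higher calls was 38.5% as deposited, 48.8% with median-of-ratios scaling and 54.9% with quantile scaling. Those at least 2-fold numbered 184 higher and 654 lower with a pseudocount of 0.1 FPKM, and 177 and 661 with limma-voom. The count of all that differed was 3171 without wild-type heat replicate 1, and the call of nitrogen remobilisation was lost with a pseudocount of 0.1 FPKM (adjusted p = 0.053). Camera called 10 lists and 0 with an estimated correlation (8 at an unadjusted p under 0.05), where the adjusted p was 0.059 for senescence-associated, heat shock, abscisic acid and anthocyanin genes, 0.078 for cytokinin, 0.12 for senescence transcription factors and chlorophyll breakdown, 0.13 for chlorophyll synthesis, 0.19 for nitrogen remobilisation and 0.2 for photosynthesis.

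The interaction tested whether the change after heat differed between the genotypes, and negative values mean a lower change in the mutant. It was negative in 15 and positive in 1 of 18 senescence-associated genes, in 11 and 2 of 22 senescence transcription factors, in 22 and 1 of 36 heat shock genes, in 8 of 9 anthocyanin genes, in 11 of 16 salicylic acid genes, in 9 of 16 jasmonate genes and in 7 of 15 nitrogen remobilisation genes, where 2 were positive. SAG13 differed by -4.03 ± 0.17 (adjusted p = 1.1e-08), PR1 by -3.45 ± 0.15 and NAC019 by -3.26 ± 0.15. It was positive in 41 of 49 photosynthesis genes (median 0.43), with LHCB2.3 at 1.02 ± 0.06 and CAB2 at 0.87 ± 0.06, and in 9 of 17 chlorophyll synthesis genes, 9 of 12 auxin and growth genes and 4 of 8 cytokinin genes. In these last lists 1, 2 and 1 members were negative. For some lists the median difference between the genotypes lay in mock and was near 0 after heat. It was 0.67 in mock and 0.0005 after heat for salicylic acid genes, and 0.39 and 0.0205 for jasmonate genes. For auxin and growth genes it was -0.56 and -0.017. Their interactions therefore include a mock level that already differed, and are not read as a changed heat response alone. With quantile scaling 26 photosynthesis genes were positive and 2 negative. Their median of 0.16 lay at percentile 86.8 of 10000 random lists matched on abundance and length. The percentile was 100 as deposited and 100 with median-of-ratios scaling. Random lists were drawn gene by gene and lack the correlation among photosynthesis genes, so a high percentile overstates the list. Chlorophyll breakdown genes were negative in 9 and positive in 2 of 13, with 5 negative with median-of-ratios scaling or without an intensity trend. The list was not called (adjusted p = 0.053), but was with quantile scaling (adjusted p = 0.013), without wild-type mock replicate 1 (adjusted p = 0.033) and without wild-type heat replicate 1 (adjusted p = 0.049). IAA29 (2.14 ± 0.18) and HFR1 (1.04 ± 0.17) were already near the floor in mutant mock, at 1.33 and 0.0592 FPKM, and the HFR1 call was lost with a pseudocount of 0.1 FPKM (adjusted p = 0.15) and with limma-voom (adjusted p = 0.45). ORE1 (-0.33 ± 0.16, adjusted p = 0.14), NAP (0.19 ± 0.19, adjusted p = 0.48) and RBCS1A (0.12 ± 0.07, adjusted p = 0.2) did not pass, and the NCED3 call (adjusted p = 0.039) was lost without any 1 library (adjusted p = 0.06 to 0.11).

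Outside the lists PHI-1 (3.74 ± 0.17), the touch-responsive TCH4 (3.25 ± 0.13), DREB26, CAF1a, DIC2 and TGG2 had the most positive interactions, and NIT2 (-6.72 ± 0.16), KTI1, ELI3-2, UPI, PDF1.3 and JRG21 the most negative. In total 5371 genes had an interaction, 1732 positive and 3639 negative, and 783 had one of at least 2-fold, 174 positive and 609 negative; the share of positive calls was 32.2% as deposited, 48.8% with median-of-ratios scaling and 52.4% with quantile scaling. Those of at least 2-fold were 220 positive and 533 negative with median-of-ratios scaling and 268 and 467 with quantile scaling. With a pseudocount of 0.1 FPKM they were 288 and 843, and with limma-voom 290 and 835. Camera called 11 lists and 0 with an estimated correlation (11 at an unadjusted p under 0.05), where the adjusted p was 0.063 for senescence-associated, heat shock, auxin and growth, jasmonate and anthocyanin genes, 0.088 for senescence transcription factors, chlorophyll synthesis and salicylic acid, 0.093 for photosynthesis and cytokinin, and 0.096 for nitrogen remobilisation.

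Adjusted over the list alone, the wild-type heat comparison gave 14 higher and 1 lower senescence-associated genes, 18 higher and 1 lower senescence transcription factors, 8 higher and 1 lower chlorophyll breakdown genes, 5 higher and 37 lower photosynthesis genes and 30 higher and 0 lower heat shock genes. In the mutant, adjusted over the list alone, the numbers were 3 higher and 2 lower, 5 higher and 0 lower, 5 higher and 5 lower, 43 higher and 0 lower and 10 higher and 1 lower. The ethylene list was not called by camera in any comparison, with 2 higher and 3 lower of 12 members after heat in the wild type and 3 higher and 5 lower in the mutant. Neither were the oxidative stress list (5 higher and 5 lower of 14 in the wild type), the circadian clock (3 and 2 of 11), the PIF-related bHLH genes (1 and 3 of 6) and cell division (3 lower of 3). Guard cell markers (1 higher and 1 lower of 6) and vascular markers (1 higher and 6 lower of 9) were not called after heat in the wild type either. The vascular list (adjusted p = 0.059) was called with limma-voom (adjusted p = 0.044) and without wild-type heat replicate 2 (adjusted p = 0.046). It was not called between the genotypes after heat or in the interaction either (adjusted p = 0.065 and 0.053), but was for the former without mutant heat replicate 1 (adjusted p = 0.026) and for the latter with limma-voom (adjusted p = 0.043) and without mutant mock replicate 2 (adjusted p = 0.017) or mutant heat replicate 1 (adjusted p = 0.025). The number of lower vascular markers in wild-type heat was 3 without wild-type heat replicate 1 or 2 and 2 without wild-type mock replicate 2. Cell division was called without wild-type heat replicate 1 (adjusted p = 0.04), but 0 of its 3 members passed without wild-type heat replicate 2 (CYCD3;1, PCNA1 and CDKB2;1, adjusted p = 0.13 to 0.18 by limma) and 1 without wild-type mock replicate 1. PCNA1 was also lost with limma-voom (adjusted p = 0.073) or without wild-type mock replicate 2 (adjusted p = 0.15). The higher clock genes numbered 1 without wild-type heat replicate 2 or without a filter on low values, 0 with quantile scaling and 5 with limma-voom. In the mutant 3 ethylene genes were lower without mutant heat replicate 1 or 2 or with median-of-ratios scaling, and 2 without mutant mock replicate 2. No shoot meristem marker passed the filter. TGG1, a myrosinase gene in the guard cell list, went from 1049 ± 1.95 to 385 ± 28.5 FPKM in the wild type. Chloroplast-encoded genes held 0.117% of summed FPKM in wild-type mock, 0.0963% in wild-type heat, 0.117% in mutant mock and 0.135% in mutant heat. Mitochondria-encoded genes held 0.0239%, 0.0325%, 0.0256% and 0.0239%. With 2 libraries against 2 an exact permutation test cannot go below p = 0.333, two-sided, so these shares are given as values.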

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

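The tests of library scaling and genotype labels for the first pattern, of scaling, of random lists under both other scalings and of harvest time for the second, and of the place of the genes and of reads gained by the MAF5 neighbours for the third were chosen only after the result was seen, as was limma-voom on recovered reads. Heat changed 816 genes at least 2-fold in the wild type and 68 in the mutant (1250 and 170 with a pseudocount of 0.1 FPKM); 5371 genes passed the interaction test, 783 of them with a difference of at least 2-fold. With median-of-ratios and quantile scaling 753 and 735 genes did, 220 and 268 of them positive against 174 as deposited. The number of interactions does not say which genotype responded less. Under these scalings heat changed 821 and 799 genes at least 2-fold in the wild type, and 78 and 76 in the mutant. That argues against scaling as the whole cause. With the reads in genes of every library thinned to a total of 14919122, 822 genes changed at least 2-fold by heat in the wild type and 59 in the mutant, a ratio of 13.9, which argues against depth. PIF5 was at most 5.603 FPKM in mutant libraries and at least 54.3 in wild-type ones, against a wrong genotype label. The genotype stays open as a biological explanation, as do a different heat dose or harvest of the mutant plants, which were not tested.

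Of 49 photosynthesis genes 37 were lower and 4 higher after heat in the wild type, and 39 higher and 0 lower in the mutant, or 23 higher without mutant mock replicate 2, 23 without mutant heat replicate 1 and 20 without mutant heat replicate 2, with list medians of -0.22 and 0.21 that were not called with an estimated correlation (adjusted p = 0.27 and 0.21). Both depended on scaling: with quantile scaling 29 members were lower in the wild type (median -0.12) and 19 higher in the mutant (median 0.0524), against 37 and 39 as deposited and 37 and 44 with median-of-ratios scaling, so scaling may account for part of either change. But quantile scaling gives all libraries the same distribution, which can also shrink a true joint shift of abundant genes. The smaller numbers under it therefore cannot tell a scaling effect from a true change. The mutant was already lower in mock in 34 of 49 members (median -0.18), or 17 with quantile scaling (median -0.0585). Its rise after heat thus started from a lower level. Genes with at least 10000 reads in a pair also varied more in mock. Their mean chi-square was 38.7 in both mock groups, 8.02 in wild-type heat and 7.62 in mutant heat. As deposited, the interaction median of 0.43 lay above all 10000 random lists matched on abundance and length (percentile 100, highest 0.35, median 0.199). With median-of-ratios scaling it did so too (0.53, percentile 100, highest 0.45). With quantile scaling it was 0.16, at percentile 86.8 of such lists. Random lists were drawn gene by gene, while the photosynthesis genes had an estimated correlation of 0.453. The random medians therefore spread too little, and a high percentile overstates the list. The scalings also disagree, so a trend with abundance stays open. Morning clock genes minus evening clock genes differed in their interaction by 0.10 for replicate 1 and 0.0697 for replicate 2, but the morning genes went both ways (from -0.43 to 0.64; evening genes from -0.46 to -0.0788), so a difference in harvest time stays open. The genotype itself stays open too.

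Between the genotypes 9 genes differed at least 4-fold in both mock and heat, among them PIF5 itself and HFR1, with 549 and 603 reads in wild-type mock and 5 and 0 in mutant mock. The 50 measured genes on each side of PIF4 and of PIF5 held 0 of the other 8, as random windows mostly do, but 4 of them (HFR1, MAF5, AT1G75945 and AT4G05275) lie on chromosomes without PIF4 or PIF5 and 3 at least 2585 measured genes from PIF5, which argues against a linked block of 50 genes on each side of either as their source. The latter, AT3G05945, AT3G06355 and AT3G06955, named after their values were seen, lie within 84 measured genes of one another; a block there was not tested, and 1 gene without a locus code was not placed. For MAF5 the summed reads of MAF2 to MAF5 gave a ratio of 1.14 in mock, which decides nothing since loss of all MAF5 reads would give only 1.28, but the neighbours gained 40.5% of the MAF5 loss in mock and -16.6% after heat, against reads moving between them as the whole cause. A second mutation or an epigenetic difference in the mutant line was not tested, and nor was direct regulation.

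The lists and genes below are given because their change after heat differed between the genotypes by the interaction test. Gene lists called by camera for it had median log2 values of -0.93 for senescence-associated genes, -0.44 for senescence transcription factors, 0.19 for chlorophyll synthesis, 0.43 for photosynthesis, -0.92 for heat shock factors and chaperones, 0.79 for auxin and growth genes, -0.39 for jasmonate, -0.64 for salicylic acid and defence, 0.58 for cytokinin, -0.33 for nitrogen and amino acid remobilisation, -2.39 for anthocyanin. None of these calls held with an estimated correlation. Chlorophyll breakdown, with a median of -0.25, was not among them (adjusted p = 0.053). The median was 0.16 for photosynthesis with quantile scaling and 0.28 for chlorophyll synthesis with median-of-ratios scaling. The log2 interaction passed for HFR1 (1.04), SAG13 (-4.03), BCB (-2.08), RNS1 (-3.93), SRG1 (-4.11), NAC019 (-3.26), WRKY45 (-1.96) and NAC047 (-2.52). It also passed for NYE1 (-0.45), ACD1 (-0.41), MES16 (-1.47), AT4G11910 (-1.41), CYP89A9 (-0.27), PORB (0.33), CHLI2 (0.32) and HEMA1 (0.37). Values past the threshold were those of CRD1 (0.50), CAB2 (0.87), LHCB2.1 (1.01), LHCB2.2 (0.73), LHCB2.3 (1.02), LHCB3 (0.64), PSAK (0.61) and HSF4 (-1.68). Further genes were HSP70 (-1.80), HSP18.2 (-2.34), AT1G53540 (-3.08), HSP101 (-1.195), ACS2 (-1.98), EFE (-0.24), ACS6 (1.67) and COR15A (0.99). The test was also passed by CYP707A1 (-1.68), NCED3 (0.44), RAB18 (-1.09), IAA29 (2.14), IAA2 (0.80), EXPA8 (0.78), SAUR22 (2.06) and SAUR23 (1.25). Also called were PDF1.2 (-3.80), OPR3 (-0.44), VSP1 (-1.68), JAZ5 (-1.13), BGL2 (-1.78), PR5 (-1.35), PR1 (-3.45) and PAD3 (-2.50). Next were CBP60G (-0.997), ARR6 (1.296), RR5 (0.88), ARR4 (0.64), NBR1 (-0.74), ATG8H (-0.52), DIN2 (-4.31) and GDH2 (-1.301). The interaction held too for NRT1.7 (-1.01), GSTF12 (-3.63), DFR (-3.73), TT4 (-2.74), LDOX (-3.15), RBOHD (-0.97), TGG1 (1.22) and ATML1 (0.39). Others past it were NIT2 (-6.72), KTI1 (-6.21), EARLI1 (-4.21), ELI3-2 (-5.91), PDF1.2c (-3.98), UPI (-5.30), TCH4 (3.25) and PHI-1 (3.74). Likewise called were TGG2 (1.94), SHY2 (1.55), XTH6 (1.54), AGP41 (1.64), LTP4 (-2.62), EXT4 (-3.39), MBP1 (-1.59) and BGLU18 (-1.52). Calls were also made for MIOX1 (0.41), FER1 (-0.42), AACT1 (-2.88), MYB47 (-0.57), QQS (-0.98), CML41 (-2.16), MDHAR (-1.45) and CAX3 (-2.73). Then came TAT3 (-1.09), ELI3-1 (0.82), SAUR19 (1.52), GolS2 (0.37), RD20 (-1.97), DIC2 (2.06), ORA47 (1.62) and CAF1a (2.06). The remaining genes were NUDT4 (1.53), WRKY40 (0.91), PP2-A5 (1.38), PDF1.3 (-4.55), CSLG2 (-4.22), DREB26 (2.65) and JRG21 (-4.39). The call was lost with quantile scaling for ATG8H (-0.37, adjusted p = 0.07), without wild-type heat replicate 2 for ATML1 (0.33, adjusted p = 0.051), with a pseudocount of 0.1 FPKM for HFR1 (adjusted p = 0.15) and NCED3 (adjusted p = 0.066), with limma-voom for HFR1 (adjusted p = 0.45), and for NCED3 also without a filter on low values (adjusted p = 0.054) or without any 1 library (adjusted p = 0.06 to 0.11). With quantile scaling PORB was at 0.19 and LHCB2.2 at 0.49.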

How the results depend on the processing

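Limma-voom on recovered reads was chosen after seeing the data and called 6668, 3677, 4302, 4730 and 5544 genes in heat in the wild type, heat in the mutant, genotype in mock, genotype after heat and the interaction. Each count stayed within 1.5 times the reported count under it and under the other pseudocount, filters, scalings, no trend, only the compared groups, library weights and the replicate block. With the replicate block the counts were 6725, 3713, 3878, 5141 and 5645. Deviations of same-numbered libraries correlated across genes between -0.0277 and 0.19 over the 6 pairs of groups, highest between the 2 mock groups. The mock pairs also had a larger mean chi-square per gene than the heat pairs, while all groups share an estimate of the spread. With only the mock groups in the fit, 2608 genes differed between the genotypes in mock, against 3479 as reported. The labels do not say that a number marks a shared batch, so the block is only an alternative. With it the vascular list was called for wild-type heat (adjusted p = 0.049) and the interaction (adjusted p = 0.046), and 2 of 486 named-gene tests lost and 1 gained a call. Requiring a 2-fold change left 816, 68, 175, 549 and 783 genes, by construction. These 2-fold counts were 1250, 170, 388, 838 and 1131 with a pseudocount of 0.1 FPKM, 1273, 176, 419, 838 and 1125 with limma-voom and 386, 30, 119, 235 and 359 with the stricter filter, which also removes list members from their counts. Leaving out 1 library, where the lone library is assumed to vary like the others, gave 4758 to 6426, 1453 to 3478, 1781 to 3236, 3171 to 4943 and 3919 to 5190 genes, with fewer samples in the fit. The correlation of heat changes ran from 0.23 to 0.30 without 1 library, genes higher in both genotypes from 297 to 491 and genes lower in both from 272 to 528. With median-of-ratios scaling genes lower in both went from 611 to 364 and genes higher in both from 506 to 718. That scaling moved the median change of all genes in mutant heat from -0.0648 to 0.0037. Lists called by camera with an estimated correlation numbered 5, 0, 1, 0 and 0 (at an unadjusted p under 0.05 10, 4, 4, 8 and 11), and with fry 22, 14, 19 and 17 in the comparisons other than mutant heat, since fry does not compare a list with other genes. In 10 of 110 list tests fry pointed the other way from camera, which called none of them by its preset correlation. Fry called 2 of them, ethylene in wild-type heat (median -0.0215) and PIF-related genes between the genotypes after heat (median 0.0996). CAB2 between the genotypes after heat was -0.0112 with quantile scaling, and the cause was not tested. The values here for genes chosen by heat are means of the 2 medians from the exchanged replicates. At 4-fold in the wild type, higher genes had 2.68 in the wild type and 0.24 in the mutant. Lower genes (7 and 4 genes) had -1.59 and 0.50. With a pseudocount of 0.1 they were 1.71, 0.22 and, for lower genes in the wild type, -1.09. Median-of-ratios scaling gave 0.22 and -0.0722 in the mutant. Higher genes chosen in the mutant at 4-fold had -0.0031 in the wild type, from medians of 0.26 and -0.26, and 1.09 in the mutant. Lower ones had -0.63 and -1.83 (1 to 6 genes in each choice). With the pseudocount of 0.1 the higher genes had 1.197 and 0.85. The cause was not tested. Without the 10 most abundant other genes the chloroplast share was 0.134, 0.109, 0.134, 0.156% and the mitochondrial share 0.0274, 0.0366, 0.0291, 0.0277% in wild-type mock, wild-type heat, mutant mock and mutant heat, since the total shrinks. A fit of only the compared groups gives no interaction, and the stricter filter gives no value for genes under a mean of 5 FPKM. Of named-gene tests 20 of 486 lost their call with median-of-ratios scaling, 18 with quantile scaling and 36 without a trend, keeping their direction. The interaction's median over all genes moved from -0.0984 to -0.0117 with median-of-ratios scaling and 0.0237 with quantile scaling. Depth limits low genes most: 1 read in a gene of 1500 bp is worth up to 0.0396 FPKM.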

Other observations

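The 4 lists below were chosen after the main results were seen, without TCH4, COR78 and COR15A, whose values had been seen, while the direction predicted for the touch list was written before its test. Cold-responsive genes were lower in the mutant under mock conditions in 9 of 9 members (median -0.82, adjusted p = 0.016 by camera with an estimated correlation). The p-values of these lists were adjusted over the 4 lists only. As COR15A had been seen lower in mutant mock before the cold list was chosen, its test is not independent of what was seen. COR15B was at a mean of 140.5 FPKM in wild-type mock and 64.2 in mutant mock, and KIN2 at 1091 and 601. After heat the wild type had fallen in 8 of 9 members, with COR15B at 67.8 FPKM and at 63.6 in mutant heat (wild-type heat, adjusted p = 0.079 with an estimated correlation). In mutant heat 3 members were lower than in mutant mock (adjusted p = 0.91). Between the genotypes after heat 6 of 9 were lower in the mutant (median -0.29, adjusted p = 0.11 with an estimated correlation), COR47 at 193 FPKM in wild-type heat and 129 in mutant heat and ERD10 at 101 and 70.5. The interaction was positive in 6 and negative in 1 (adjusted p = 0.065). LTI30 rose after heat in the wild type, at 4.37 and 19.3 FPKM in wild-type mock and heat. Genes of aliphatic glucosinolate synthesis, defence compounds of the cabbage family, rose after heat in 8 of 11 members in the wild type (adjusted p = 0.079 with an estimated correlation) and fell in 5 in the mutant (adjusted p = 0.17), with a negative interaction in 9 (adjusted p = 0.065 with an estimated correlation). Between the genotypes 4 were higher in mutant mock (adjusted p = 0.13) and 8 lower in mutant heat (adjusted p = 0.1). Indole glucosinolate genes had 3 higher and 1 lower of 7 members after heat in the wild type (adjusted p = 0.43).

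TCH4, PHI-1 and DREB26 were high in wild-type mock and mutant heat and lower in the other groups, TCH4 at 47.9, 10.7, 17.5 and 40.9 FPKM in wild-type mock, wild-type heat, mutant mock and mutant heat. As TCH4 responds to touch, handling of the leaves at harvest may differ between the groups. In the list of other touch and early wound genes 7 of 14 had a positive and 3 a negative interaction (median 0.33). Camera with the preset correlation called the list for the interaction (adjusted p = 0.0014), but with an estimated correlation it did not stand apart (adjusted p = 0.28). The preset correlation also called it in mutant heat (adjusted p = 7.0e-10) and between the genotypes after heat (adjusted p = 2.0e-06) and in mock (adjusted p = 0.035), but not in wild-type heat (adjusted p = 0.68). The design gives no record of handling, so a difference in handling stays open. Under mock conditions 8 members were higher and 3 lower in the mutant (median 0.34, adjusted p = 0.37 with an estimated correlation), opposite to TCH4, and in wild-type heat 5 were higher and 6 lower (adjusted p = 0.86). In mutant heat against mutant mock 11 members were higher (adjusted p = 0.17 with an estimated correlation), including ERF104 at 30.7 and 66.1 FPKM and TCH2 at 23.54 and 39.1, and between the genotypes after heat 8 were higher and 1 lower in the mutant (median 0.55, adjusted p = 0.11). JAZ7 was at 4.80 and 3.00 FPKM in mutant mock and heat.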
